A study of Drosophila melanogaster with 14 samples.

How the data were processed

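The series holds 14 samples of Drosophila S2 cells grown at 27 °C: RDD contact libraries for roX2 and 7SK, RNAPII ChIA-PET libraries and RNA-seq libraries. Per the labels, control, heat-shock (37 °C for 20 min) and recovery cells (20 min at room temperature afterwards) were aliquots of 1 culture in exponential growth. The submitters' processing notes name BWA, Picard, MACS2, STAR, RSEM and the build dm3, with no versions and no order of use. The labels name total RNA as the extract, but whether it was then selected by its poly(A) tail and whether the RNA-seq counting used strand are not given in the sources used here, so genes that overlap on opposite strands cannot be told apart.

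Peaks were called with MACS 2.2.6 per library without pooling and without a control sample, keeping all duplicates, with no fragment model, a fragment length of 200 bp and a q-value threshold of 0.05, per the file headers. The same headers give a genome size of 1.2e+08 for RDD and 2.7e+09, a setting for human, for RNAPII. That setting enters the expected background and with it the q values, so the numbers of RNAPII peaks and their overlaps with roX2 and 7SK peaks rest on it and are not comparable with the RDD peak numbers. Each peak has a pileup signal (tags over the summit, not scaled for depth), a fold enrichment over the local background of the same library, and −log10 p and q values, all as the authors' caller wrote them. Per the file headers each library's tag number was read, from 6.86 M (RNAPII heat shock) to 25.2 M (7SK replicate 2), where 1 M is 1000000. The deposited cluster files list 2 anchors and the PET count joining them, whole-number counts that the authors did not normalize. They list clusters of 2 PETs or more with anchor midpoints at least 2.46 kb apart when on 1 chromosome, and the clustering tool is not given in the sources used here. A version made with a 50 bp tag extension was deposited for some libraries and served as an alternative. The RNA-seq files hold the authors' RSEM estimated counts and TPM per gene, the latter scaled to 1000000 per library.

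From these files each library's share of peaks, of intrachromosomal clusters and of their PETs on the X chromosome was computed, with the median distance between anchor midpoints. Replicate 2 of each RNA was represented by its deep run, the standard and deep runs being 1 library. roX2 (3 labelled replicates) and 7SK (2) were compared with exact two-sided permutation tests of the difference in means. The two-sided p is 2 times the smaller one-sided p, so the smallest p is 0.2. Whether labelled replicates were separate was checked by counting clusters of 2 PETs with anchors identical to the base, and values with replicates 1 and 2 counted as 1 sample are given beside the tests. Peaks were called shared at an overlap of at least 1 bp and clusters when both anchors overlapped by at least 1 bp. Chance overlap was the mean over 100 circular shifts of 1 list along each chromosome. Intervals are 95% exact binomial (Clopper-Pearson) intervals and cover counting error only. Changes of contact loci between conditions used PETs per 1000000 clustered PETs of each library, over loci with at least 10 PETs in 1 of the 2 libraries, with overlapping clusters joined. Because this minimum admits more loci through the deeper library, the counts were repeated with its PETs drawn at random 11 times until both libraries held as many clustered PETs, dropping clusters left with under 2.

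RNA-seq had 1 library per condition, so no test was made and no p-value is given for a gene. Changes are log2 differences of TPM + 1, which understate the change of low genes, over genes with at least 50 estimated counts in 1 of the 2 libraries, and are reported relative to the median tested gene. Genes past a fixed size of 2-fold were counted. Estimated counts divided by median-of-ratios size factors were an alternative. Each fixed gene list was set against 10000 random lists of the same size matched on mean TPM in 20 bins, and percentiles describe these libraries only. Lists covered heat shock, dosage compensation, P-TEFb/7SK/pausing, RNA polymerase II, immediate early and stress kinase, oxidative stress, unfolded protein, antimicrobial, hemocyte, neuron, muscle, fat body, germline, cell cycle, ecdysone, ribosomal protein, replication histone, glycolysis, mitochondrial genome and X-linked genes. The mitochondrial list matched 0 genes, and Hop, Nelf-B and Lz were not matched. Gene names came from the files, and chromosomes, for 16959 of 17039 genes, from a reference table of Release 6, whose coordinates were not used. The counting rule for rises was tested on simulated counts for heat shock against control. It found 100% of 100 genes raised 8-fold, 92% of 100 genes raised 3-fold and 0% of 6616 unchanged genes. These were Poisson counts around the control values, with no lowered genes, no other variation between libraries and no length trend. The simulation therefore does not show how many unchanged genes pass the rule in the real libraries.

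The tests, gene lists, alternatives and the rule for named items were fixed before the data were examined. By that rule the text names the 12 largest rises and 12 largest falls per RNA-seq contrast, members of the heat shock, dosage compensation and P-TEFb/7SK/pausing lists with at least 50 counts, the 5 highest-scoring peaks and the 5 clusters with most PETs in the deepest control library of each factor, and the 5 loci with the largest rise and fall per contact contrast. Examples of these are printed, and other list members, chosen after their values were seen, illustrate their lists. Centring on the median gene, the length adjustment in 20 bins, the restriction to single-copy genes with an effective length of at least 100 bp, sums over gene copies, thinning of the deeper contact library and counting replicates once were chosen after the data had been seen. Single-copy genes here are those whose names fall outside fixed families such as histones, Hsp70, snRNA and rRNA. Their copy number was not checked, so genes that share reads with others can remain. Linking contacts to genes was not run, because no annotation of dm3 was used here. Alternatives covered peak and PET thresholds, overlap rules, tag extension, run, replicate block, leaving out replicates, pseudocount, count minimum and scaling.

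The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Depth limits single contacts: clusters of 2 PETs make up most of each list, and matches of such clusters between libraries depend on depth.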

Results

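Chromatin contacts in complexes pulled down with 2 noncoding RNAs were mapped in Drosophila S2 cells, a male, hemocyte-like line first grown from late embryos. In the assay (RDD), chromatin was crosslinked and sonicated, complexes of 1 RNA were pulled down with antisense probes, and DNA ends brought together in those complexes were joined through a linker and sequenced as paired-end tags (PETs). The RNAs were roX2, part of the MSL complex that raises transcription of the single male X chromosome, and 7SK, the small nuclear RNA that holds the elongation kinase P-TEFb inactive. RNA polymerase II (RNAPII) contacts were mapped by ChIA-PET, and RNA was sequenced. Of 14 samples, roX2 had 3 labelled control replicates (replicate 2 with a standard and a deep run) and 1 heat-shock library. The roX2 replicate 3 and the roX2 heat-shock library, and no others, are labelled as saturated sequencing. For 7SK there were 2 labelled replicates (replicate 2 again with both runs). RNAPII and RNA-seq had 1 library each for control cells, heat shock (37 °C for 20 min) and recovery (a further 20 min at room temperature). The contact libraries held 6.86 to 25.2 M tags (1 M is 1000000), and the RNA-seq libraries held 8.19, 10.9 and 10.8 M estimated counts in control, heat shock and recovery. Coordinates are those of the build dm3. Conditions with 1 library have no replicate check and no test, and their intervals are 95% exact binomial (Clopper-Pearson) intervals, which cover counting error only.

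Replicates 1 and 2 of each RNA held contacts in common at a level that separate libraries lacked. Of 24505 clusters of 2 PETs on the main arms in roX2 replicate 1, 4728 (19.3%) had the same anchors to the base in the standard run of replicate 2, against 25.2% between the standard and deep runs of replicate 2 itself and 0 of 24505 with replicate 3. For 7SK the share between replicates 1 and 2 was 19.7%, and between the runs of replicate 2 it was 26.8%. Replicates 1 and 2 were therefore also counted as 1 sample. Values over the labelled replicates are given first (roX2 n = 3, 7SK n = 2), with the value after counting replicates 1 and 2 once (roX2 n = 2, 7SK n = 1) beside them. Nothing in the labels says that replicates came from separate cultures, so their spread may be technical.

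The first comparison asked where on the genome each RNA lies. Chromatin bound by roX2 was concentrated on the X chromosome, and chromatin bound by 7SK was not. The X held 36.1% ± 0.783 (SD, n = 3) of roX2 peaks and 14.0% ± 0.508 (SD, n = 2) of 7SK peaks. It held 47.2% ± 6.20 of the intrachromosomal roX2 contact clusters against 10.6% ± 0.158 for 7SK, and 58.6% ± 1.46 of their PETs against 10.8% ± 0.0560. RNAPII clusters of control cells placed 9.96% (9.83 to 10.1%) on the X. Among roX2 clusters of at least 10 PETs, the X share was 97.2%, 89.2% and 77.2% in replicates 1, 2 and 3.

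The 3 differences were 22.1, 36.6 and 47.7 percentage points, each many times the spread between replicates, and each had p = 0.2 by an exact two-sided permutation test that doubles the smaller one-sided p, the smallest value such a test can give for 3 against 2 libraries. Counting replicates 1 and 2 once, the X shares for roX2 were 36.2% ± 0.372, 45.5% ± 7.21 and 58.9% ± 1.29 (SD, n = 2) against 14.0%, 10.6% and 10.8% in 7SK, with no test made. At 5 PETs or more per cluster the difference in the X share of clusters rose to 56.1 points.

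**Figure D1:**
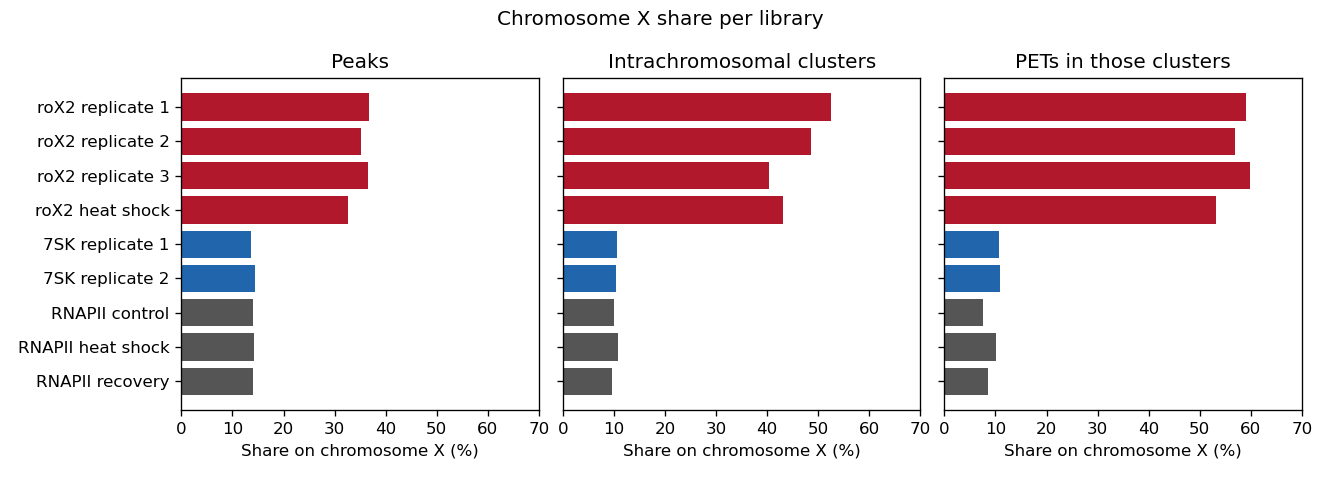
Bars give the share on chromosome X (%) of peaks, of intrachromosomal contact clusters and of the PETs in those clusters, 1 bar per library, from 0. The roX2 control bars for clusters lie between 40.4 and 52.5%, the heat-shock bar at 43.1%, and the 7SK and RNAPII bars under 11%.

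The strongest roX2 contacts formed short-range domains along the X. In replicate 3, the deepest control library, the cluster with most PETs joined X 12600213–12674198 to 12606220–12680476 with 4508 PETs. The clusters that matched it held 543 PETs in replicate 1 and 1466 in replicate 2, each summed over several clusters. No single cluster there held more than 178 and 497 PETs. Next in replicate 3 came X 1750156–1821450 to 1755870–1825074 with 3089 PETs and X 16480737–16527660 to 16496010–16534902 with 1725. They were followed by X 6113030–6153097 to 6122653–6158521 with 1492, and X 12520569–12549099 to 12529394–12553324 with 1428. In each of these 5 clusters the 2 anchors are broad and overlap each other. The 5 highest-scoring roX2 peaks all lay on the unplaced sequence Uextra, at the authors' fold enrichments of 29.7 to 48.6. Of the peaks of replicate 3, 13.1% lay on the unplaced sequences U and Uextra. For 7SK the highest-scoring peak was 3R 3299412–3300995, with a fold enrichment of 15.5 in replicate 2 and 17.1 in replicate 1. The 7SK cluster with most PETs joined 3L 8666697–8696995 to 8675962–8708839 (569 PETs), followed by 3L 626360–636276 to 637234–649315 (203 PETs) and 3R 25596580–25606026 to 25604300–25613462 (118 PETs). Genes at these positions were not assigned, because no annotation of build dm3 was used here.

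roX2 peaks were found again across independent libraries far more often than roX2 contacts. Between replicates 2 and 3, which share no contacts base for base, 84.4% (83.5 to 85.4%) of the peaks of replicate 2 were overlapped, against 7.82% when positions were shifted along each chromosome. Of its contact clusters, 10.9% (10.6 to 11.2%) had both anchors matched, against 2.12% after shifting. The X carried this overlap, with 21.7% of X clusters matched and 0.563% of autosomal ones. Both anchors lay on peaks of the same library in 26.1 to 32.2% of X clusters and in 0.558 to 0.860% of autosomal clusters over the 3 roX2 control replicates. For replicates 1 and 2 the shares were 97.8% of peaks and 60.2% of clusters in roX2, and 97.7% and 58.7% in 7SK, which the common contacts raise.

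Over all chromosomes, though not on the X, 7SK peaks coincided with RNAPII peaks more often than roX2 peaks did. RNAPII peaks of control cells overlapped 57.2% ± 0.116 (SD, n = 2) of 7SK peaks and 46.0% ± 1.08 (SD, n = 3) of roX2 peaks, a difference of -11.1 points for roX2 minus 7SK (p = 0.2, exact two-sided permutation test, the smallest possible). Counted once, the roX2 mean was 46.3% ± 1.26 (SD, n = 2). After shifting, 42.3 to 44.8% of 7SK peaks and 38.5 to 39.4% of roX2 peaks still overlapped. On the X, 56.3 to 58.4% of roX2 peaks lay on RNAPII peaks (41.3 to 43.4% after shifting), next to 55.5 and 56.3% of 7SK peaks (36.6 and 39.3% after shifting). On the autosomal arms the shares were 44.2 to 48.3% for roX2 (43.3 to 44.1% after shifting) and 58.5 to 58.6% for 7SK (44.5 to 47.3% after shifting).

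The spans of the contacts were long and variable for both RNAs. The median distance between anchors was 1423 ± 743 kb (SD, n = 3) for roX2 and 780 ± 230 kb (SD, n = 2) for 7SK, a difference smaller than the spread of the roX2 replicates (p = 0.4, exact two-sided permutation test). Counted once, the roX2 mean was 1256 ± 711 kb (SD, n = 2). Without roX2 replicate 2 the difference was 244 kb and without replicate 3 it was 978 kb, against 643 kb with all libraries. At 5 PETs or more per cluster it was 31.6 kb over all chromosomes, but the autosomal spans of these clusters were 1387 to 2724 kb in the 3 roX2 replicates against 13.2 and 59.6 kb in 7SK, and the X spans were 5.57 to 34.1 kb against 19.6 and 60.1 kb.

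After heat shock roX2 was still concentrated on the X, and its contacts were shorter. In the heat-shock library 43.1% (42.6 to 43.6%) of intrachromosomal clusters lay on the X, within the 40.4 to 52.5% of the controls, and 32.7% (31.8 to 33.7%) of its peaks did, under the 35.2 to 36.7% of the controls. Its median contact span was 68.1 kb against 753 to 2222 kb, and intrachromosomal contacts made up 62.1% of its clusters against 42.9 to 45.8%. The X domain at 12600213–12680476 held 14917 of every 1000000 clustered PETs after heat shock, against 7976, 6097 and 7214 in control replicates 3, 2 and 1. X 1750156–1825074 held 3534 against 5466, 4105 and 4690, so the size of this fall depends on the control used. Strong contacts of replicate 3, those of at least 10 PETs, were matched in the heat-shock library in 49.4% (46.6 to 52.3%) of cases, next to 48.0% (45.2 to 50.9%) in control replicate 2.

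The difference in the X share of clusters from the control mean was -4.07 points. It was -8.52 points against replicates 1 and 2 at standard depth, nearest in tags, but 2.73 points against replicate 3 alone. Replicate 3 is deeper, but it is the control that shares the saturated-sequencing label of the heat-shock library. In clustered PETs the deep run of replicate 2 lies nearest (240451 against 198362), and the X held 48.6% of its clusters. For peaks -3.43 points turned to 7.99 points in the upper 50% of peaks by score. With clusters of at least 5 PETs the control spans exceeded the heat-shock span by 34.9 kb over all chromosomes, against 1355 kb with clusters of any PET number. Among clusters of at least 5 PETs the shortening lay on the autosomal arms, at 86.2 kb after heat shock against 1387 to 2724 kb in the controls. On the X the span was 17.8 kb, within the 5.57 to 34.1 kb of the controls. Such autosomal clusters seldom recurred even between controls. Of those in replicate 3, 27 of 2277 (1.19%) were matched in control replicate 2, against 877 of 3499 (25.1%) on the X. The autosomal shortening thus describes clusters that were mostly not found again.

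**Figure D2:**
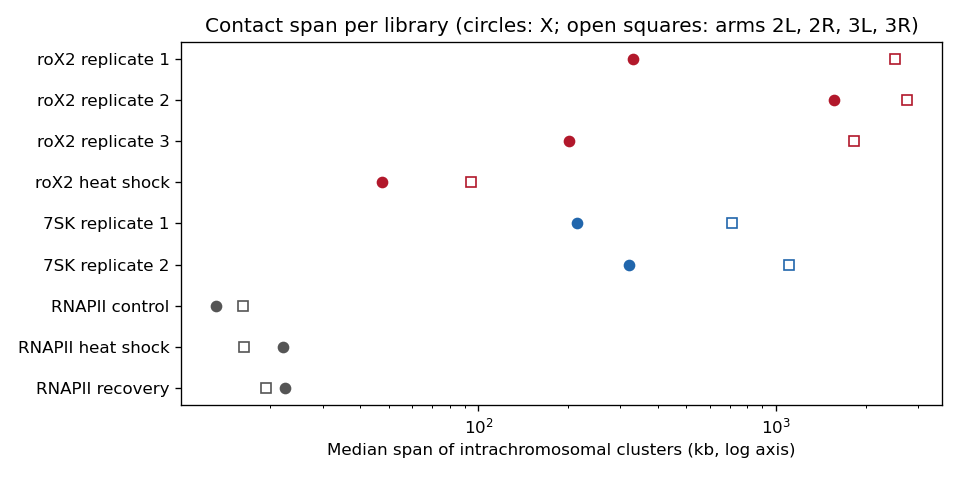
Median span of intrachromosomal clusters per library (kb, log axis), filled circles for X and open squares for the arms 2L, 2R, 3L and 3R. The roX2 heat-shock library lies at 47.6 kb on X and 94.3 kb on the autosomal arms, below every roX2 control library, the lowest of which lie at 201 and 1827 kb.

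Fewer autosomal than X-linked roX2 sites of control cells were found again after heat shock. Of the X peaks of control replicate 3, 70.9% (69.0 to 72.6%) were found after heat shock and 69.6% (67.8 to 71.4%) in control replicate 2. Of its autosomal peaks, 52.0% (50.2 to 53.7%) were found after heat shock against 71.1% (69.5 to 72.7%) in control replicate 2. Among 1742 contact loci with at least 10 PETs in either library, 1216 of them on the X, 571 held at least 2-fold more of every 1000000 clustered PETs after heat shock and 761 at least 2-fold less. This balance depends on depth: with replicate 3 thinned at random until both libraries held as many clustered PETs, 545 of 1044 loci were higher and 257 lower (medians of 11 thinnings). Most calls before thinning rest on presence alone. Of the 761 loci lower, 618 had no cluster in heat shock, and of the 571 higher, 478 had none in replicate 3. After thinning, 496 loci had none in replicate 3 and 71 had none in heat shock (medians). No such count was made between control libraries, where 48.0% of replicate 3 clusters of at least 10 PETs were matched in replicate 2. The next largest gains in share were X 5795213–5807702 to 5801630–5812203 (1226 to 2485 by the same measure) and X 7201258–7217258 to 7208742–7225246 (950 to 2132). The next largest losses were X 20262585–20286914 to 20270973–20305871 (1276 to 403) and X 19743145–19757784 to 19749142–19766018 (1695 to 1084).

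RNAPII contacts were fewer in the heat-shock and recovery libraries, while some loci gained share. Control, heat-shock and recovery libraries listed 209397, 102289 and 168528 clusters and 67259, 58291 and 68406 peaks. At 3L 640698–654884 to 644368–662737, RNAPII PETs per 1000000 clustered PETs went from 807 in control to 1806 in heat shock, and at 3R 25609567–25624109 to 25613484–25633375 from 517 to 1289. At 3L 8666475–8690688 to 8672444–8696263, which overlaps the leading 7SK contact, they went from 1042 to 1563, with 1016 in recovery. The largest losses were at 2R 1612665–1620333 to 1621674–1636337 (1150 to 720) and 2L 16437882–16452216 to 16444195–16456260 (490 to 218), and 3L 8065293–8072287 to 8072837–8075749 fell from 319 to 59.7.

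Of 10380 RNAPII loci with at least 10 PETs in control or heat shock, 591 were at least 2-fold higher and 4225 at least 2-fold lower after heat shock, and of 10563 loci 400 were higher and 4387 lower in recovery. Most loci entered through the deeper control library, and 2341 were not listed at all in heat shock against 47 not listed in control. With the control thinned at random until both libraries held as many clustered PETs, the counts were 334 higher and 1863 lower of 4496 loci in heat shock, and 351 and 2889 of 6798 in recovery (medians of 11 thinnings). Yield differed too, with 6.55, 4.15 and 4.88 clustered PETs for every 100 tags, and per 1000000 clustered PETs the number of clusters was 1.45 and 1.47 times the control in heat shock and recovery, so the direction of the change in cluster number depends on the scaling.

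RNAPII sites were found again more often than RNAPII contacts. Of the control peaks, 73.2% (72.8 to 73.5%) were overlapped in heat shock and 81.8% (81.6 to 82.1%) in recovery, against 28.6 and 33.9% after shifting. Control clusters were matched in 14.0% (13.9 to 14.2%) and 20.8% (20.66 to 21.01%) of cases, against 8.30 and 12.6%. Clusters of at least 5 PETs were matched by any cluster in 49.1% (48.5 to 49.6%) and 62.0% (61.5 to 62.6%). Median spans were 15.8, 16.8 and 19.5 kb in control, heat shock and recovery, contacts over 1 Mb made up 2.95, 8.42 and 7.73% of clusters, and the X share of clusters was 9.96, 10.8 and 9.53%. The X share of PETs was 7.64, 10.1 and 8.60%, and median spans were 13.1, 22.0 and 22.4 kb on the X against 16.1, 16.4 and 19.3 kb on the autosomal arms.

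Hsp70, Hsp68 and small heat shock protein RNAs were higher after 20 min at 37 °C and, by TPM, higher still in recovery. Summed over its 6 near-identical copies, Hsp70, the main inducible chaperone, stood at 424 TPM in control, 2846 in heat shock and 16126 in recovery. Hsp68, a close relative, stood at 96.6, 1168 and 3673 TPM, and the small heat shock proteins Hsp26 at 506, 4526 and 7167 and Hsp23 at 233, 1743 and 4206. Relative to the median gene, Hsp26 changed by -0.28 from heat shock to recovery, against 0.70 for Hsp68 and 0.32 for Hsp23. The Hsp70 co-chaperone stv was reached late, at 1.12, 2.26 and 32.5 TPM. Of 21 measured heat shock genes 8 were at least 2-fold higher in heat shock and 0 lower, and of 23 in recovery 12 were higher and 0 lower, relative to the median gene and with each Hsp70 copy counted. As a set the list was past random lists in recovery more than in heat shock: its median was 0.65 in heat shock (86.0th percentile of 10000 random lists of like expression, or 97.9th among lists also matched on length), with Hsf and Droj2 below the median gene, and 1.58 in recovery (100th percentile), or 0.93 in recovery when the Hsp70 copies were summed.

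These RNA changes are given relative to the median tested gene, because the median log2 change of TPM was 0.46 for heat shock against control, 1.52 for recovery against control and 0.95 for recovery against heat shock. On plain TPM each change is higher by that shift, which turns the sign of small falls, such as the medians of the antimicrobial, glycolysis, P-TEFb and ribosomal lists in recovery against control. Genes of effective length under 100 bp took 65.7, 39.0 and 29.9% of all TPM in control, heat shock and recovery, led by 7SLRNA:CR32864 with 24.3% in control. Long transcripts were lower in heat shock and higher in recovery: the shortest 10% of genes had a median relative change of 0.77 and then -0.76.

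**Figure D3:**
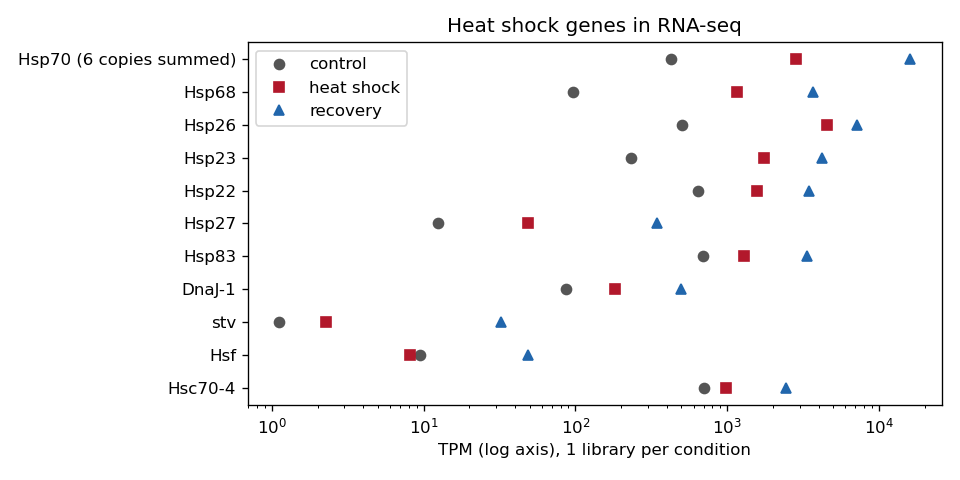
TPM (log axis) of heat shock genes in control, heat shock and recovery, 1 library per condition, 1 point per gene and library. Hsp70 summed over 6 copies runs from 424 to 2846 and 16126 TPM, while Hsc70-4, a chaperone made at all times, runs from 703 to 985 and 2439.

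Replication histone RNA was far higher after heat shock. Of 94 measured histone genes 87 were at least 2-fold higher and 1 was lower relative to the median gene, with a list median of 3.79. Summed over copies, His4 stood at 398, 14008 and 12582 TPM in control, heat shock and recovery, His3 at 325, 6491 and 8697, His2A at 113, 9958 and 9648, His1 at 37.2, 860 and 624, and His2B at 458, 1239 and 714. In recovery 62 of 81 were higher than in control and 7 lower (median 2.93), and against heat shock 0 of 93 were higher and 69 lower (median -1.38, or 0.039 after removing the length trend). Summed over copies and relative to the median gene, His2B changed by 0.98 in heat shock and -0.88 in recovery against control. The other families changed by 2.51 (His1) to 4.88 (His2A) in recovery against control. From heat shock to recovery His3 changed by -0.53 on that scale, though its TPM rose. Copies are nearly identical, so the estimate for a single copy is uncertain.

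Genes of replication and mitosis were higher as a list, though not each of them. Of 12 cell cycle genes 5 were at least 2-fold higher in heat shock and 9 in recovery, with 0 lower in both, CycE (0.03) and dup (0.24) near the median gene in heat shock, and list medians of 0.95 (99.97th percentile) and 1.247 (99.99th). Among them Mcm5, a subunit of the replicative helicase, stood at 4.57, 22.8 and 33.3 TPM, and string (stg), the phosphatase that triggers mitosis, at 6.12, 17.4 and 136 TPM.

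Most glycolysis RNAs fell after heat shock. Of 12 genes 8 were at least 2-fold lower and 0 higher, with a median of -1.25 (0th percentile), and Gapdh1 alone lay above the median gene (0.51, from 66.2 to 131 TPM). Ldh, lactate dehydrogenase, went from 106 to 4.13 TPM and stayed at 8.78 in recovery, while the hexokinase Hex-A went from 12.1 to 2.13 and then to 58.2. The trehalose transporter Tret1-1 (50.1 to 6.54 TPM), Sytalpha (26.3 to 0.53), MFS3 (24.8 to 1.59), CG15784 (110 to 10.3) and Orct2 (47.5 to 8.45) were also among the 12 largest falls of single-copy genes. In recovery against control 3 glycolysis genes were lower and 0 higher (median -0.09), and in recovery against heat shock 6 were higher and 1 lower (median 0.77, 98.4th percentile, or 99.67th among lists also matched on length).

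By log2 difference of TPM + 1, TotM had the largest rise of the single-copy genes after heat shock. With size factors lncRNA:alphagamma-element:CR32865 (5.68, from 11 control counts) and CG13559 (5.61, from 2) rose more than TotM (5.45). TotM, a stress-induced secreted protein, went from 265 to 15548 TPM in heat shock and 11071 in recovery. On TPM + 1 it was followed among others by CG18549 (9.70 to 141), Hsp68 and Gel (45.0 to 440). The antifungal peptide Drs stood at 536, 10558 and 6297 TPM. Of the 12 antimicrobial genes 5 were measured. Of these 3 were higher and 0 lower in heat shock, with a median of 1.51 (99.3rd percentile, or 95.9th among lists also matched on length). With no count minimum that median was -0.18. In recovery 1 was higher and 2 lower (median -0.44). In recovery against heat shock 0 were higher and 4 lower (median -1.69, 0.09th percentile, or 8.04th matched on length). After removing the length trend, Drs (2.93) and PGRP-SD stayed at least 2-fold higher in heat shock, while DptB came to 0.60. AttB (-1.39) and CecA1 (-1.20) were then at least 2-fold lower. None of the 4 falls in recovery against heat shock stayed past 2-fold after that adjustment. The list of the 12 largest rises without the single-copy restriction held identical histone His2A copies and snRNA:U2:34ABa, whose TPM rests on a very small effective length, so single-copy genes are named here, a choice made after these values were seen.

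Collagen and laminin genes were among the largest single-copy rises in recovery, and no list of such genes was tested as a set. The collagen chains vkg and Col4a1 went from 16.7 and 18.7 TPM in control to 44.1 and 48.3 in heat shock and 837 and 859 in recovery, and the laminin LanB2 went from 9.45 to 474 and Glt from 0.61 to 76.8 in recovery. Tep2 (17.9 to 668), teq (13.3 to 483) and prc (0.43 to 47.0) were among the 12 largest rises too. Of 8 hemocyte genes, which mark the lineage this line resembles, 6 were higher and 0 lower in recovery (median 1.72, 100th percentile), 2 higher and 0 lower in heat shock (median 0.81, 99.98th), and 5 higher and 0 lower in recovery against heat shock (median 1.16, 99.3rd, or 49.9th among lists also matched on length). Most of these are long transcripts, and after removing the length trend vkg still changed by 3.30 and Col4a1 by 3.46 on the log2 scale in recovery against control, while Ppn came to 0.37 and Hml to -1.10, which is 2-fold lower. In recovery against heat shock vkg and Col4a1 alone of the 5 hemocyte genes stayed 2-fold higher after that adjustment, and Hml was lower at -1.25. From heat shock to recovery, Act5C, a cytoplasmic actin, went from 84.2 to 1432 TPM and the myosin heavy chain zip from 5.16 to 86.8, while Prosalpha1, a proteasome subunit, went from 149 to 41.03.

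roX2 RNA was lower in recovery, and of the mRNAs for its protein partners Clamp alone was at least 2-fold lower. lncRNA:roX2 stood at 2454, 2180 and 693 TPM in control, heat shock and recovery, a change of -3.35 relative to the median gene in recovery, or -2.48 after removing the length trend, which gives -1.54 in heat shock. The helicase mle stood at 1.71, 1.39 and 14.7 TPM and msl-2 at 3.16, 2.18 and 13.8, while the adaptor Clamp stood at 57.1, 54.3 and 55.7, a relative change of -1.56. Of 8 measured dosage compensation genes 0 were higher and 0 lower in heat shock (median -0.63, 4.29th percentile), 1 was higher and 2 lower in recovery (median 0.28), and 5 were higher and 1 lower in recovery against heat shock (median 1.24, 99.1st percentile, or 96.6th among lists also matched on length). After removing the length trend none of those 5 stayed 2-fold higher, roX2 (-1.08) and Clamp (-1.43) were 2-fold lower in that contrast, and mle, the 1 gene higher in recovery against control, came to 0.54. lncRNA:roX1 had 7, 13 and 18 counts and was left out. RNA of X-linked genes moved little, with medians of -0.10 over 1166 genes in heat shock (20.4th percentile), 0.11 over 1206 in recovery (99.98th) and 0.20 over 1208 in recovery against heat shock (99.93rd, or 88.0th among lists also matched on length).

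7SK itself did not follow the heat shock genes. snRNA:7SK stood at 59836, 84097 and 80455 TPM, a relative change of 0.03 in heat shock and -1.09 in recovery, where plain TPM is above control. After removing the length trend these were -0.88 and -0.23, so the direction for this short RNA depends on the scaling. Its inhibitor protein Hexim stood at 5.15, 16.5 and 14.9 TPM, and the P-TEFb subunit CycT at 3.64, 1.64 and 23.4. In heat shock Hexim was the 1 gene of 12 in the P-TEFb and pausing list that was at least 2-fold higher, and CycT and Nelf-A (3.60 to 1.46 TPM) were lower (median 0.22, 68.4th percentile). After removing the length trend these 3 changes were 0.89, -0.70 and -0.83, none of them 2-fold. In recovery 2 of 13 were higher and 2 lower (median -0.11), of which Trl alone (1.10) stayed past 2-fold after removing the length trend. In recovery against heat shock 4 were higher and 4 lower (median -0.13), of which CycT alone (1.07) stayed past 2-fold after that adjustment.

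Ribosomal protein RNAs kept pace with the median gene in heat shock and fell behind it in recovery, but lagged genes of like length in both. Of 85 genes 1 was higher and 0 lower in heat shock (median 0.05, 0th percentile), 5 were higher and 45 lower in recovery (median -1.04, 0th percentile), and 7 were higher and 50 lower in recovery against heat shock (median -1.09, 0.90th percentile). These transcripts are short. After removing the length trend the list median was -0.63 in heat shock and -0.36 in recovery. Among lists also matched on length these lay at the 0th and 0.035th percentiles. In recovery against heat shock the list turned to the 99.47th percentile among lists also matched on length, with a median of 0.17 after removing the length trend.

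**Figure D4:**
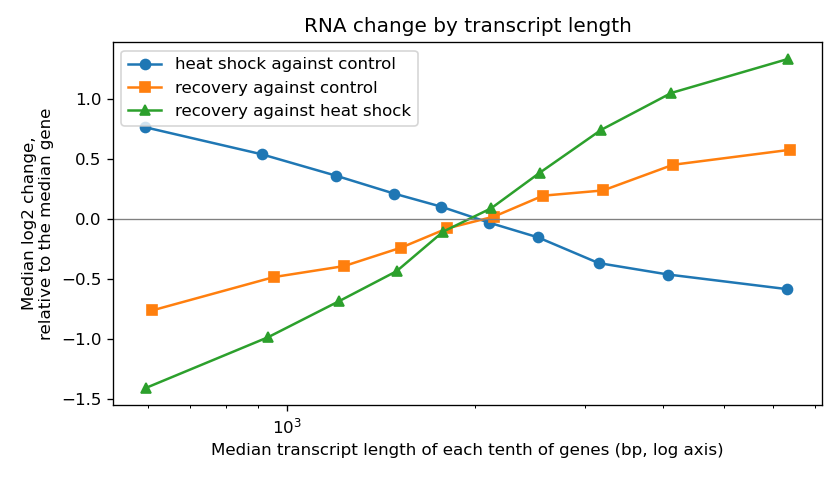
Median log2 change relative to the median gene (y axis) of 10 equal groups of tested genes ordered by transcript length (x axis, bp, log axis), 1 line per contrast. The group of shortest transcripts lies at 0.77 in heat shock and -0.76 in recovery against control.

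Markers of other cell types stayed low. The neuronal gene elav had 427, 272 and 584 estimated counts in control, heat shock and recovery and brp had 44, 43 and 74, the muscle gene Mlc2 had 77, 41 and 29, and the germline gene bam had 37, 50 and 88. The neuronal genes nSyb and Syt1, the muscle genes Mhc, up and Act88F, the fat body genes Fbp1, Lsp1alpha and Lsp2, and the germline genes vas and nos had under 50 counts in all 3 libraries. Several hemocyte genes were also low in control cells, with Hml at 90 counts, PPO1 at 63, Sr-CI at 27 and Pxn at 22. The hemocyte genes NimC1 and He had under 50 counts in all 3 libraries. Others were higher in control, with srp at 366, Ppn at 852, vkg at 3414 and Col4a1 at 3657. Low counts alone therefore do not set the other markers apart from hemocyte ones.

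Counted over all genes at a fixed rule of at least 2-fold on TPM, 1773 of 7042 were higher and 154 lower in heat shock, 5135 of 7214 were higher and 55 lower in recovery, and 3510 of 7236 were higher and 108 lower in recovery against heat shock. Relative to the median gene these became 799 and 554, 1041 and 1035, and 1627 and 1268, and with size factors on estimated counts 1030 and 932, 1487 and 1270, and 1899 and 1851. Relative to genes of like length they were 535 and 425, 913 and 768, and 752 and 302. These 3 scalings set the middle of the genes near 0 by construction, so they do not show whether RNA rose or fell overall.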

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

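The tests of fragment length, sequencing depth, random ligation, untailed RNA, summed copies and heat shock itself were chosen after the results were seen; only the test of transcript length within ribosomal protein genes was chosen before its result was known.

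RNA change followed transcript length in opposite directions in the heat-shock and recovery libraries, which drew attention because the shortest 10% of genes moved by 0.77 in heat shock and -0.76 in recovery against the same control, a difference that was not tested. Shorter fragments as the whole cause are argued against, since implied fragment lengths were 298, 278 and 267 bp in control, heat shock and recovery, shorter in both conditions, while the shortest 10% moved to -0.76 in recovery. A length-dependent recovery of RNA that differed between libraries may account for it: within 85 ribosomal protein genes, regulated together, rho with length was -0.32 in heat shock (permutation p = 0.00299), 0.46 in recovery and 0.63 in recovery against heat shock (p = 1e-05 for both, the smallest the permutations can give), across genes that are not independent replicates. Heat shock itself, with rho of -0.51 over all 7042 genes, cannot be told apart from a library effect with 1 library per condition.

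roX2 contacts were shorter after heat shock, with a log2 ratio of median spans of -4.39 against the control mean, while for RNAPII it was 0.086; the difference between these was not tested. Sequencing depth is argued against as the cause. The control libraries next below and next above heat shock in tags (7.48 and 11.6 M against 9.38) had median spans of 1295 and 1691 kb. In clustered PETs (198362 in heat shock) the neighbours were the runs of replicate 2 (126138 and 240451), at 1691 and 2222 kb. Replicates 1 and 2 count as 1 sample here, so this rests on 1 independent control. The other control, the deeper replicate 3 (565169 clustered PETs), lay at 753 kb. A smaller share of random ligation could give fewer long contacts and stays open: autosomal contacts over 5 Mb per interchromosomal contact were 1.65 times the value for randomly paired ends, but the controls gave 1.51 to 1.64 and 7SK 1.59 to 1.67, so the bound set for random pairs was wrong for every library and decides nothing. Per 100 interchromosomal clusters, autosomal clusters over 5 Mb numbered 16.7 in heat shock and 14.7 to 15.2 in the control runs. Those of 20 kb to 1 Mb numbered 33.8 against 10.4 to 12.2. On the X the values were 6.99 against 6.11 to 12.5 over 5 Mb and 28.1 against 9.10 to 12.8 at 20 kb to 1 Mb. On the autosomes the shorter median thus went with more near contacts per interchromosomal contact, not with fewer long ones. Heat shock itself, at 68.1 kb in 1 library, cannot be told apart from that library's preparation.

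Replication histone RNA, 3.88 higher in median on the size-factor scale, was weighed because most are made without a poly(A) tail. A gain of untailed RNA as a whole is argued against, since 14 other untailed RNAs had a median change of -0.87 in heat shock, with 0 at least 2-fold higher and 7 lower. Those 14 RNAs are shorter, with a median length of 285 bp against 529 bp for the histone genes. Whether untailed RNA of histone length was kept to a different extent was therefore not tested. Reads split between identical copies are argued against as well, because estimated counts summed over all copies changed by 3.90 (10327 to 186490). Heat shock itself remains a hypothesis, as 1 library per condition, with a median of 2.97 in recovery, cannot be told apart from a difference between these libraries.

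Contacts between chromosomes, which the X shares of clusters leave out, also touched the X more often in roX2 libraries, with an X end in 17.7% ± 2.19 (SD, n = 3) of interchromosomal cluster ends against 12.96% ± 0.355 (SD, n = 2) in 7SK (p = 0.2, exact two-sided permutation test, the smallest possible), and 17.1% when replicates 1 and 2 were counted once.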

How the results depend on the processing

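Centring on the median gene, length matching and adjustment, single-copy genes, summed copies, replicates counted once, standard-depth controls, thinned libraries and the span at 5 PETs were chosen after the data were seen; the other alternatives were planned. Of the alternative values, 243 were labelled the same, which means within 1 SD of the replicates or the width of the 95% interval to 1 side, within 1.5 times for counts, and on the same side of the outer 2.5% for lists. With wide replicate spread this covers distant values, such as spans of 31.6 and 244 kb beside 643 kb. A further 74 moved, 12 were no longer past their threshold, 3 newly were, and 5 reversed; where no cause is named, the cause was not tested. The signs of the differences between roX2 and 7SK held under all alternatives run.

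For roX2 against 7SK, the difference in X share of peaks was 28.4 points on the main arms alone and 19.9 in the upper 50% of peaks by score. That of clusters was 56.1 at 5 PETs or more, and that of PETs was 73.7 at 5 PETs or more, 43.0 with a 50 bp extension and 34.7 at spans of at least 20 kb. The difference in RNAPII overlap was -8.85 when 50% of the smaller peak had to overlap. Leaving out 1 replicate gave ranges of 21.7 to 22.6 points for peaks, 33.9 to 39.97 for clusters, 47.1 to 48.5 for PETs, -11.7 to -10.7 for RNAPII overlap and 244 to 978 kb for span. With a replicate block over numbers 1 and 2, the differences were 21.9, 39.97, 47.1 and -11.7 points and 978 kb, all of the same sign as without it; the numbers pair nothing in the labels.

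Replicate overlaps of peaks and clusters moved with the rule. In the upper 50% of peaks by score they were 99.3% (roX2 1 and 2), 93.8% (1 and 3), 89.8% (2 and 3) and 95.7% (7SK), and with 50% of the smaller peak overlapping 89.5% (1 and 3), 83.3% (2 and 3) and 97.3% (7SK). For clusters of at least 5 PETs they were 90.0, 70.2, 36.7 and 79.8%, and with anchors within 1 kb 61.8, 21.8, 14.9 and 60.3%.

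After heat shock, the difference in X share of roX2 clusters was -12.3 points at 5 PETs or more. It was 2.73 with replicate 3, also labelled as saturated sequencing, as the control and -8.52 with controls at standard depth. That of peaks was 7.99 in the upper 50% by score. Leaving out control replicates gave -7.46 to -1.38 for clusters and -3.88 to -3.15 for peaks. The control minus heat-shock span was 34.9 kb at 5 PETs or more over all chromosomes. Loci at least 2-fold higher and lower in heat shock than in replicate 3 came to 545 and 257 with replicate 3 thinned to the same clustered PETs, so falls no longer outnumbered rises. The share of replicate 3 clusters matched in heat shock and in control replicate 2 was 16.5 and 15.6% at 5 PETs or more, 1.24 and 1.18% with a 50 bp extension and 6.98 and 5.63% with anchors within 1 kb.

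With the RNAPII control thinned in the same way, loci higher and lower came to 334 and 1863 in heat shock and 351 and 2889 in recovery, with falls still the more frequent. RNAPII cluster numbers relative to control were 0.265 (heat shock) and 0.420 (recovery) at 5 PETs or more and 1.45 and 1.47 per 1000000 clustered PETs. Control clusters were matched in 15.5 and 23.7% at 5 PETs or more in both lists and 29.9 and 42.0% with anchors within 1 kb. Control peaks were overlapped in 66.0 and 71.7% in the upper 50% by score and 72.4 and 81.1% at 50% of the smaller peak.

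RNA-seq counts moved with the scaling. Higher and lower genes in heat shock were 1030 and 932 with size factors, 799 and 554 relative to the median gene and 535 and 425 relative to genes of like length; a pseudocount of 5 gave 1126 and 49, a pseudocount of 0.1 gave 337 lower, and 1.5-fold gave 3065 and 481. In recovery they were 1487 and 1270, 1041 and 1035, and 913 and 768 under the same 3 scalings, with 32 lower at a pseudocount of 5, 92 lower with no filter and 128 lower at 1.5-fold. In recovery against heat shock they were 1899 and 1851, 1627 and 1268, and 752 and 302, with 358 lower at 1.5-fold.

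Among gene lists, matching random lists on length as well left each median as it was and moved its percentile. Ribosomal proteins in recovery against heat shock (-1.09) turned from the lower to the upper side of random lists, at the 99.47th percentile, which is counted as reversed. The heat shock list in heat shock (0.65) came to the 97.9th, and these left the outer 2.5%: unfolded protein (-0.54) and antimicrobial (1.51) in heat shock, and in recovery against heat shock dosage compensation (1.24), immediate early (1.11), unfolded protein (1.43), antimicrobial (-1.69), hemocyte (1.16), ecdysone (1.23), histones (-1.38) and X-linked genes (0.20). With no filter, antimicrobial reversed to -0.18 in heat shock and came to -1.60 in recovery, ecdysone came to -0.68 in heat shock and 0.95 in recovery against heat shock, and immediate early to 0.39 in the latter. Ribosomal proteins in heat shock reversed to -0.037 at a pseudocount of 0.1, and the heat shock list in recovery was 0.93 with copies summed.

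RNAPII occupancy and contacts at genes, and expression of genes at contact anchors, were not run, since no annotation of dm3 was used here. Depth limits contacts of 2 PETs, of which few recur between libraries, and TPM of genes with effective lengths under 100 bp.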

Other observations

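The test of 7SK marking below was chosen before its result was known, and the comparisons of heat-shock peaks with 7SK peaks were chosen after the data were seen.

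The roX2 heat-shock library listed many autosomal peaks that no roX2 control library listed, and these lay mostly on 7SK peaks of control cells. Of the heat-shock roX2 peaks, 3465 autosomal and 1032 X-linked ones were in no control library. The autosomal ones overlapped 7SK peaks in 73.4% (71.9 to 74.9%) and RNAPII peaks in 61.8% (60.1 to 63.4%) of cases, while the 1877 autosomal heat-shock peaks that a control library also listed overlapped 7SK peaks in 40.3% (38.1 to 42.6%). The X-linked new peaks did not share this, with 38.2% (35.2 to 41.2%) on 7SK peaks and 52.1% (49.0 to 55.2%) on RNAPII peaks, against 44.7 and 62.8% of the X peaks that a control library also listed, though for RNAPII the values after shifting also differed, at 29.4 and 40.5%. Over all autosomal roX2 peaks the share on 7SK peaks was 61.8% (60.5 to 63.1%) after heat shock, with 15.1% after shifting, and 25.2 to 28.9% in the 3 control replicates, with 17.0 to 17.4% after shifting. The new autosomal peaks were weaker, with a median fold enrichment of 2.71, against 3.67 for the autosomal heat-shock peaks that a control library also listed. The heat-shock set is 1 library whose peaks were called without a control sample. Binding by roX2 at these places therefore cannot be told apart from other signal in that pull-down.

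Most changes of the other fixed gene lists did not stand apart from lists of like length. Unfolded protein response genes had a median of -0.54 in heat shock (0.28th percentile, or 2.735th matched on length), 0.47 in recovery and 1.43 in recovery against heat shock (99.7th, or 94.3rd matched on length), with the chaperones Hsc70-3 at 87.4, 130 and 966 TPM and Gp93 at 36.9, 36.8 and 374. Ecdysone response genes had medians of -0.69, 0.42 and 1.23 (98.0th, or 74.2nd matched on length) in the same order, and Eip75B stood at 6.05, 4.92 and 61.5 TPM. Immediate early and stress kinase genes had medians of 0.06, 0.01 and 1.11 (99.4th, or 93.8th matched on length), with kay, the fly Fos, at 33.3, 69.8 and 474 TPM. Oxidative stress genes had medians of 0.07, 0.02 and -0.16, with Sod1 at 189, 658 and 527 TPM. The 5 RNA polymerase II genes had medians of 0.05, -0.44 and -0.72, though the largest subunit RpII215, a long transcript, stood at 6.71, 5.30 and 57.3 TPM.

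RNAPII contacts that gained share in heat shock included loci near leading 7SK contacts, which led to the hypothesis that 7SK contacts in control cells mark such loci. The test, which matched loci on mean PETs, went against it. Leaving out the 10 named loci, 2881 of 10370 RNAPII loci were matched by a 7SK cluster of replicate 2, and their median log2 change of -0.30 lay at the 0.005th percentile of random loci of the same mean PETs, whose median was -0.23. Without matching, marked loci fell less than unmarked ones (-0.30 against -0.44) and more of them rose (36.1 against 30.9%). Loci matched by roX2 replicate 3 clusters also lay low, at the 0.07th percentile, so the position was not particular to 7SK.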
